A study of Mus musculus with 6 samples.

How the data were processed

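Polyadenylated RNA was sequenced from 6 libraries of mouse embryonic fibroblasts on day 2 of reprogramming towards pluripotency. Per the labels, the cells came from the strain CBA/CaJ X C57BL/6J and were transfected with short hairpin RNAs (shRNAs) in the chemically defined medium iCD1, with or without ethanolamine (Etn). Per the labels' protocols, 1 μg of RNA was selected for poly(A), copied to cDNA, given indexed adapters, amplified by 12 cycles of PCR and read as 2 x 100 paired ends. The deposited table gives 1 RPKM value (reads per kilobase of gene, scaled to the size of the library) per gene and library, as made by the authors. Bowtie 0.12.2 and genome build mm10 are named per the submitters' processing notes. The gene models, the counting program, the strand setting and any filter are not given in the sources used here.

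The table held 18303 genes, none on the mitochondrial chromosome, and every value column could be assigned to a library. For all 18303 genes the values of the 6 libraries stood in ratios of whole numbers once the relative depth of the libraries was allowed for, within 1e-05 reads plus a relative 5e-09. The smallest such numbers were taken as the reads behind each value, and the transcript length was inferred from RPKM per read. Whether they count reads or pairs is unknown. Reads in genes came to 20020465 and 19535038 for shLuc replicates 1 and 2, 19623532 for shEtnk1/2, 19233255 for shPcyt2, 18467583 for Etn-deprived and 18484272 for shPebp1. Intervals on single values are 95% Poisson intervals from the recovered reads and cover counting error only. Names that a spreadsheet had turned into dates stood on 26 lines of the table and were kept as they were, and 2 symbols stood on 2 lines each, of which the one with the higher mean was used.

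Genes with a mean of at least 1 RPKM over the 6 libraries were tested, 11939 in all, with a median transcript length of 2926 nt and a median of 701 reads. Values were analysed as log2(RPKM + 1), which understates the fold change of genes with low values. Each library was compared with shLuc by limma, with a trended and robust empirical Bayes step, in a model of 5 group means. The treated groups held 1 library each, so the spread came from the shLuc pair alone, with 1 residual degree of freedom and a prior of 9.24, and each treated library was assumed to vary as shLuc did. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A size rule without a test counted the genes at least 1 log2 unit above or below both shLuc libraries. The 3 libraries that inhibited the CDP-ethanolamine pathway (shEtnk1/2, shPcyt2 and Etn-deprived) were also compared as 1 group with shLuc in a limma fit of 2 groups, with 3 residual degrees of freedom and a prior of 6.37. That comparison has 10 splits, so the least permutation p it allows is 0.1. Differences between treatments were tested in the model of 5 group means, with 1 library on each side and the spread again from the shLuc pair alone.

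The comparisons, the tests, the rule for named genes and 26 gene lists were fixed before the data were examined. The lists covered the CDP-ethanolamine pathway, other phospholipid synthesis, mesenchymal genes, epithelial genes, the reprogramming factors, pluripotency genes, NF-kB targets, autophagy, TGF-beta targets, the cell cycle, endoplasmic reticulum stress, the integrated stress response, cholesterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, the interferon response and p53 targets. Further lists marked macrophages, endothelial cells, skeletal muscle, neural and glial cells, keratinocytes, cartilage, adipocytes, mitochondrially encoded genes and replication-dependent histones. Lists with at least 3 measured members, 22 of them, were tested. In the comparison of 3 against 2 libraries they were tested by camera (limma) with a preset correlation between genes of 0.01, and again with an estimated correlation. For single libraries the median of a list was placed among 10000 random lists of the same size, matched on expression. The difference between the shLuc libraries was treated in the same way and serves as background.

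Named genes were the 4 targeted genes, the 5 furthest up and 5 furthest down past the size rule in each single comparison (10 and 10 in the pathway comparison), up to 4 members with the largest differences from each list described, and a fixed panel of Cdh1, Epcam, Snai1, Snai2, Zeb1, Zeb2, Thy1, Fn1, Pou5f1, Sox2, Klf4 and Nanog. The RNA was selected for poly(A), and how well the values measure small RNAs was not tested. Genes past the size rule proved to be mostly small RNAs with few reads. A further choice was therefore made after the values had been seen, of the 10 largest changes in each direction among genes that limma called and that were not small RNAs, together with members of the lists that limma called. Gene Ontology terms were taken from the deposited table, and terms of 10 to 500 genes were counted among called genes. Treatments were compared by Pearson r across genes, beside r for simulated libraries that were unchanged but shared the same controls.

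The fits were tested on simulated data with 11939 genes and 200 changed genes in 10 runs. The limma fit recovered 68.9% of 2-fold and 23.1% of 1.5-fold changes, with 11.9% false calls among those made and 1.6 calls on average in an unchanged library. The share of false calls was therefore above the nominal threshold. Alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter or a mean of 5 RPKM, quantile normalization, scaling to a common median ratio, the sum of the values of a symbol, plain empirical Bayes and leaving out libraries. Alternatives added after the data had been seen were a minimum of 50 mean reads, the removal of small RNAs (under 200 nt), adjustment for trends with transcript length or with GC content and length, limma-voom on the recovered reads, leaving out treated libraries in the list tests, and fits without shLuc replicate 2. GC values were held for 95.5% of the tested genes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.

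A few single genes that were members of the lists or among the genes called are not reported here; list counts and medians include them.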

Results

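The series set out to learn how the CDP-ethanolamine pathway, which makes phosphatidylethanolamine, acts on the transition from mesenchymal to epithelial cells early in reprogramming. RNA was sequenced from 6 libraries in 5 groups. The control group held 2 libraries with an shRNA against luciferase (shLuc). The other groups held 1 library each. These were shEtnk1/2, directed at both ethanolamine kinases, shPcyt2, directed at CTP:phosphoethanolamine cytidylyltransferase, Etn-deprived, with shLuc in medium lacking Etn, and shPebp1, directed at phosphatidylethanolamine-binding protein 1. Reads in genes ranged from 18467583 to 20020465 per library. No treated group had a replicate, so none of its differences had a replicate check of its own. Nothing in the labels says that the shLuc replicates were separate cultures, so p measures only the spread between these samples. A library with shPebp1 in medium lacking Etn is mentioned in the series text and was not analysed here.

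The first comparison asked whether each shRNA lowered its target. Etnk1 (ethanolamine kinase 1; mm10 chromosome 6, 143167230 to 143208547) fell in the shEtnk1/2 library to 12.5 RPKM (95% interval 11.9 to 13.2), which was 59.1% of the shLuc mean. The shLuc libraries had 21.0 and 21.4 RPKM, and the change was -0.71 (SE 0.09, limma, Benjamini-Hochberg adjusted p = 0.00401). Etnk2 (chromosome 1, 133363572 to 133380319) lay below the filter and was not tested, with 15 reads in shEtnk1/2 (45.6% of the shLuc mean in RPKM) against 21 and 45 in shLuc, which themselves lay far apart. Pcyt2 (chromosome 11, 120610087 to 120617890) had 29.9 RPKM (28.1 to 31.8) in the shPcyt2 library against 42.0 and 40.0 in shLuc. This was 72.9% of the shLuc mean and did not pass the test (-0.44, SE 0.08, adjusted p = 0.16), though it did with limma-voom (adjusted p = 0.0161), with at least 50 reads (adjusted p = 0.0265) and without small RNAs (adjusted p = 0.0416). Pebp1 (chromosome 5, 117282651 to 117287564) had 99.6 RPKM in shPebp1 and 250.4 in shLuc replicate 1, but 100.7 in the library labelled shLuc replicate 2. The other libraries had 229.1 (shEtnk1/2), 263.4 (shPcyt2) and 210.5 RPKM (Etn-deprived). Against shLuc replicate 1 the shPebp1 library was at 39.8%, and against the library labelled shLuc replicate 2 its log2 difference was -0.02.

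**Figure D1:**
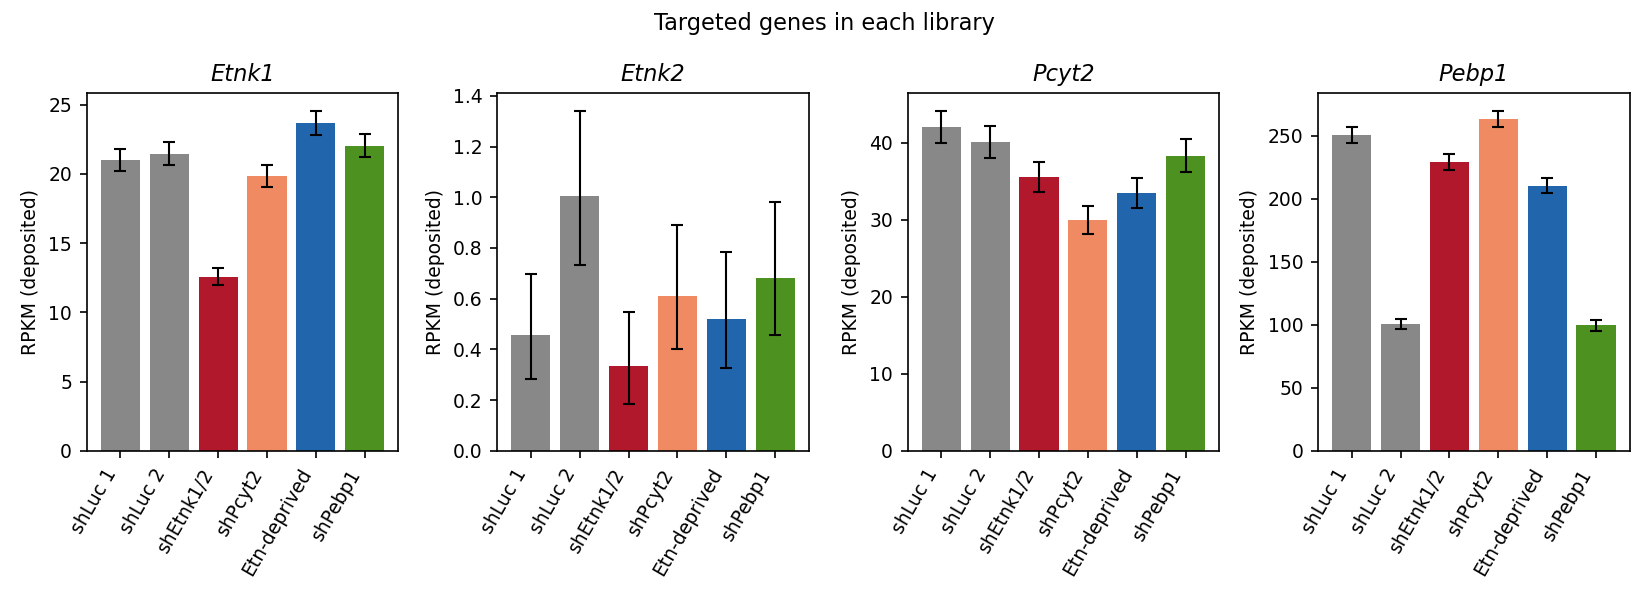
RPKM of the 4 targeted genes in each of the 6 libraries, with bars from 0 and 95% Poisson intervals that cover counting error only. Etnk1 was at 12.5 RPKM in shEtnk1/2 against 21.0 and 21.4 in shLuc, and Pebp1 was at 99.6 RPKM in shPebp1 and at 100.7 in the library labelled shLuc replicate 2.

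The shEtnk1/2 library asked what shRNAs against the ethanolamine kinases do to the cells, with Etnk1 lowered in part and Etnk2 below the filter. Some mesenchymal genes, among them genes of the extracellular matrix, rose (11 of 32), and some epithelial genes (4 of 13) and 3 reprogramming factors fell. Of 32 mesenchymal genes, 31 were higher than the shLuc mean, with a median log2 difference of 0.31, at percentile 100 among random lists. The limma test called 11 of them, or 19 adjusted over the list alone. They included Postn (periostin), at 345.6 RPKM against 169.7 and 200.6 in shLuc (0.90, SE 0.10, adjusted p = 0.0141), the proteoglycans Lum (0.62, SE 0.06, adjusted p = 0.00154) and Dcn (0.55, adjusted p = 0.0193), and the collagen gene Col1a1 (0.57, adjusted p = 0.00291). The contractile genes Tagln (0.72, SE 0.26) and Acta2 (0.64, SE 0.24) had large differences that did not pass the test. Of 13 measured epithelial genes, 11 were lower, with a median of -0.33 (percentile 0), and 4 fell, or 8 adjusted over the list alone, which also called 1 as higher. Cdh1 (E-cadherin) fell from 10.9 and 9.35 RPKM to 6.04 (-0.65, SE 0.12, adjusted p = 0.0215; 9.71e-06 to 0.526 over its alternatives). Spint2 and St14, a protease inhibitor and an epithelial protease, fell by 0.68 and 0.63. Cldn3 (-0.72) and Cdh3 (0.64) did not pass the test.

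Of the 4 reprogramming factors, Sox2 (-0.55, SE 0.06, adjusted p = 0.00291), Klf4 (-0.53, adjusted p = 0.00552) and Pou5f1 (-0.53, adjusted p = 0.00533) fell in shEtnk1/2 and were also the 3 called when adjusted over the list alone. Myc differed by -0.11. The table does not separate transgenes from endogenous copies. Pluripotency genes were hardly expressed, with 5 of 26 measured (median -0.15, percentile 18.6), and Nanog lay below the filter. TGF-beta targets had a median of 0.25 (percentile 100), with 15 of 18 higher, and the 2 called were Id3 (0.44, adjusted p = 0.0121) and the integrin gene Itga11 (0.57, adjusted p = 0.0164). Adjusted over the list alone, 9 were higher and 1 lower. Interferon response genes had a median of 0.29 (percentile 100), and 2 of 21 were called, or 6 adjusted over the list alone. These 2 were the chemokine gene Cxcl10 (1.17, SE 0.21, adjusted p = 0.0198) and Rtp4 (0.56, adjusted p = 0.0261). In the background comparison, shLuc replicate 2 against replicate 1, this list had a median of -0.09 (percentile 1.2). Neural and glial genes had a median of -0.37 (percentile 0), with 2 of 7 called, or 3 adjusted over the list alone. Among them was Stmn2 (-0.45, adjusted p = 0.0191). Cell cycle genes were lower in 27 of 28 cases, with a median of -0.15 (percentile 0.3), and only Mcm7 was called (-0.31, adjusted p = 0.0475).

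From the choice made after the values had been seen, the genes that rose most in shEtnk1/2 included the small leucine-rich proteoglycans Ogn (0.82), Kera (0.81) and Aspn (0.72), the tendon gene Tnmd (0.77), Lrrc15 (0.75), Spp1 (osteopontin, 0.73), Angptl1 (0.85), the growth factor gene Ntf3 (0.97) and the water channel gene Aqp5 (0.96). Those that fell most included Trh (-1.24), Acsbg1 (-1.23), Tmprss5 (-1.22), Cml3 (-1.14), Msc (-1.09), Dio3 (-1.04), Fetub (-1.04), the transcription factor gene Cebpd (-1.02), Mapt (tau, -0.95) and Avil (-0.95). Among genes that rose, collagen fibril organization counted 10 of its 34 genes where 0.4 was the number a random choice gives, wound healing 10 of 48 (0.5) and cell adhesion 15 of 191 (2.1); with the length trend removed the first 2 terms passed (adjusted p = 9.52e-07 and 2.88e-07) and cell adhesion did not.

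In all, limma called 413 genes in shEtnk1/2, 130 higher and 283 lower. Scaling to a common median ratio gave 138 higher and 102 lower, quantile normalization 81 and 72, and limma-voom 336 and 454, the median of all genes in this library being -0.06. With the trend in length removed 94 genes were called, and with GC content and length 176. The median log2 difference of the 130 higher calls stayed at 0.48, while the prior degrees of freedom went from 9.24 to 6.03 and 7.07. Of the list members called, 8 of 11 mesenchymal, 0 of 4 epithelial, 3 of 3 reprogramming factors, 1 of 2 TGF-beta and 0 of 2 interferon genes stayed called with length removed, and 9, 1, 3, 2 and 2 with both. With length removed Cdh1 was at -0.67 (adjusted p = 0.0663) and Dcn at 0.55 (adjusted p = 0.0517), and Tnmd, Spp1, Ntf3, Aqp5, Stmn2 and Mcm7 also missed the threshold. Without the library labelled shLuc replicate 2, with the spread taken from the other pathway libraries, 5 genes were called (514 at an unadjusted p under 0.05), 1 of them among the 413. The size rule took 26 genes, of which 16 were small RNAs with few reads. Against 1 shLuc library alone it took 68 and 66, beside 55 between the 2 shLuc libraries. Its leading genes were Mir5133 (2.38), Mir335 (2.21), Mir7647 (2.20), Mir6481 (2.02) and Cxcl10 among those higher, and Snord69 (-3.23), Mir6385 (-2.12), Mir25 (-1.83), Mir6948 (-1.74) and Mir7027 (-1.63) among those lower.

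**Figure D2:**
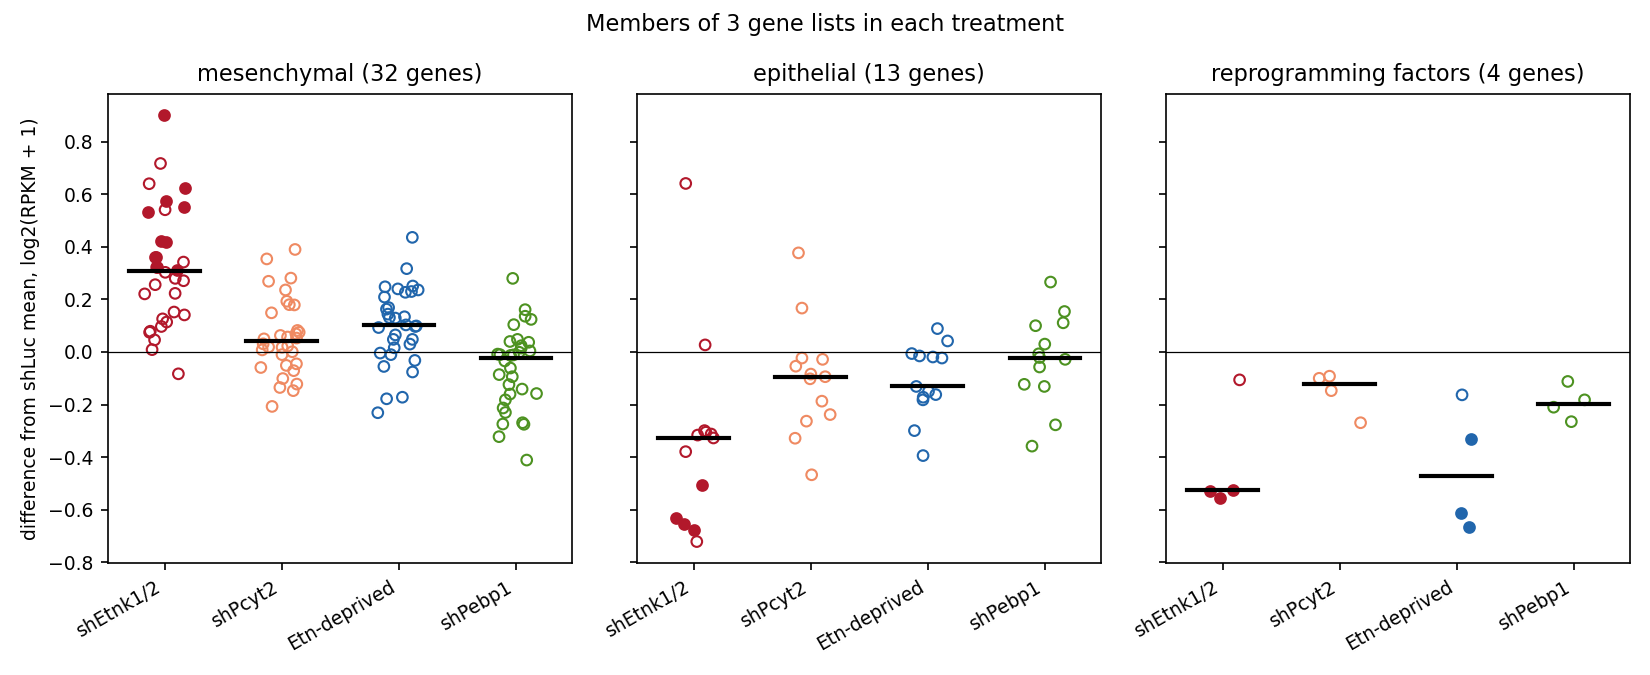
Log2(RPKM + 1) differences from the shLuc mean for members of the mesenchymal (32 genes), epithelial (13) and reprogramming factor (4) lists in each treated library, with filled points for genes that limma called and bars at the medians. The mesenchymal median was 0.31 in shEtnk1/2 and 0.10 in Etn-deprived, and the reprogramming factor medians in these libraries were -0.53 and -0.47.

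The shPcyt2 library asked the same of the next enzyme of the pathway. Few genes were called, by a fit that recovered 23.1% of simulated 1.5-fold changes. Pcyt2 itself was still at 72.9% of the shLuc mean. Gm5148, a predicted gene singled out after its values were seen, rose from 24.5 and 24.4 to 44.8 RPKM (0.85, SE 0.09, adjusted p = 0.00306), and the other 12 of the 13 genes called by limma, 6 higher and 7 lower in all, were small RNAs. Gm5148 went the other way in shEtnk1/2 and Etn-deprived, where limma called it lower. TGF-beta targets had a median of 0.15 (percentile 100), with 13 of 18 higher, among them Cdkn2b (0.36) and Id3 (0.36), and none passed the test over all genes while 2 did adjusted over the list alone. Interferon response genes had a median of 0.09 (percentile 99.8), with Cxcl10 at 0.49, and against shLuc replicate 1 alone a median of -0.01 (percentile 68.8). The reprogramming factors had a median of -0.12 (percentile 0.3), with Klf4 at -0.27 (SE 0.07, adjusted p = 0.478), Sox2 at -0.15 and Pou5f1 at -0.10, and 1 was called adjusted over the list alone. Mesenchymal and epithelial genes had medians of 0.04 (percentile 90.6) and -0.09 (percentile 8.1). Past the size rule were 16 genes, all small RNAs with a mean under 50 reads. Highest were Mir301 (2.81), Mir7026 (2.28), Mir5119 (2.21), Snord42b (1.81) and Mir335 (1.64). Lowest were Mir3061 (-2.47), DQ267100 (-1.94), Snord93 (-1.91), Snord100 (-1.83) and Snord95 (-1.74). Without the library labelled shLuc replicate 2, with the spread taken from the other pathway libraries, limma called 0 genes (172 at an unadjusted p under 0.05), and limma-voom on all libraries called 37. Most of the 13 genes called by limma were not among those 37.

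The Etn-deprived library asked what removal of the pathway's substrate does. The reprogramming factors Klf4 (-0.67, SE 0.07, adjusted p = 0.00111), Sox2 (-0.61, SE 0.06, adjusted p = 0.000884) and Pou5f1 (-0.33, SE 0.07, adjusted p = 0.0283) fell, the same 3 when adjusted over the list alone, with Myc at -0.16 and a list median of -0.47 (percentile 0). Interferon response genes had a median of 0.33 (percentile 100), with 17 of 21 higher. Of these 21, 2 were called, among them Rtp4 (0.68, SE 0.11, adjusted p = 0.00962), or 7 adjusted over the list alone. Against shLuc replicate 1 alone this median was 0.16 (percentile 99.8). Mesenchymal genes had a median of 0.10 (percentile 100), with 24 of 32 higher and none called, or 5 adjusted over the list alone; Postn was at 0.44 and Pdgfra at 0.32. Epithelial genes had a median of -0.13 (percentile 4.2), with Cdh1 at -0.01 (SE 0.12). Of 25 oxidative phosphorylation genes 5 fell, or 8 adjusted over the list alone, among them Ndufa1 (-0.63, adjusted p = 0.00385), Ndufb8 (-0.48, adjusted p = 0.017) and Cox5b (-0.45, adjusted p = 0.0108). The list median of -0.09 (percentile 13.9) lay within the range of random lists, but at percentile 1.6 against shLuc replicate 2 alone.

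Other members that passed the test in the Etn-deprived library were Id1, a TGF-beta family target, at -0.49 (SE 0.07, adjusted p = 0.00635), Alpl, alkaline phosphatase, from the pluripotency list, at -0.55 (adjusted p = 0.0205), the chemokine gene Ccl7 at 0.55 (adjusted p = 0.00951), Idi1 of cholesterol synthesis at 0.38 (adjusted p = 0.0235), Lamp2 of lysosomes at 0.33 (adjusted p = 0.0258) and Ccng1, a p53 target, at 0.29 (adjusted p = 0.0436). From the choice made after the values had been seen, the cytoskeletal genes Myl6 (from 736.5 and 705.9 to 317.1 RPKM; -1.18, SE 0.06) and Tmsb10 (-1.28, SE 0.09) and the complex I genes Ndufa2 (-1.01) and Ndufa12 (-0.98) fell, as did Rpl39l (-1.32), Naa38 (-1.30), Gadd45gip1 (-1.09), Rnf113a1 (-0.98), Tceal5 (-0.96) and Polr2l (-0.93). Ly96 (0.90, SE 0.13), an accessory protein of the endotoxin receptor, Tnmd (0.75), Spp1 (0.67) and Nucb2 (0.63) rose. The genes that fell counted 37 of 139 genes of translation where a random choice gives 4.4 (adjusted p = 2.33e-21), and 4 where it gives 0.3 once the length trend was removed, which did not pass (adjusted p = 0.363). The other term that passed was ATP synthesis coupled proton transport, with 6 of 16 where 0.5 is given (adjusted p = 0.00411), and no term passed once the length trend was removed.

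In all, limma called 454 genes in the Etn-deprived library, 70 higher and 384 lower, where limma-voom gave 294 and 406. The median transcript of those lower was 1006 nt long against 2926 nt for all tested genes. Genes of up to 700 nt had a median of -0.28 in this library and those over 5000 nt 0.04, and the difference was also ordered by GC content (Spearman rho -0.52 across genes, which are not independent replicates). With the length trend removed 40 genes were called (14 higher, 26 lower), and with GC content and length 59 (12 and 47). Called both ways were Sox2, Klf4, Rtp4, Ly96, Nucb2, Myl6, Tmsb10, Ndufa2, Ndufa12, Rpl39l, Naa38, Gadd45gip1 and Polr2l. Pou5f1 (adjusted p = 0.138 and 0.335; 0.00021 to 0.744 over its alternatives), Ndufb8, Cox5b, Id1, Alpl, Idi1, Lamp2, Ccng1, Rnf113a1, Tceal5, Tnmd and Spp1 were called neither way, Ccl7 with length removed alone and Ndufa1 with both removed alone. Without the library labelled shLuc replicate 2, with the spread taken from the other pathway libraries, 20 genes were called (896 at an unadjusted p under 0.05), 10 of them among the 454. The size rule took 33 genes, 26 of them small RNAs, led by Mir335 (2.43), Mir5119 (1.53), Mir31 (1.49), Mir6935 (1.29) and DQ267100 (1.29) among those higher, and by Mir1839 (-3.64), Snord93 (-1.91), Mir196b (-1.87), Mir1964 (-1.77) and Mir7027 (-1.63) among those lower.

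**Figure D3:**
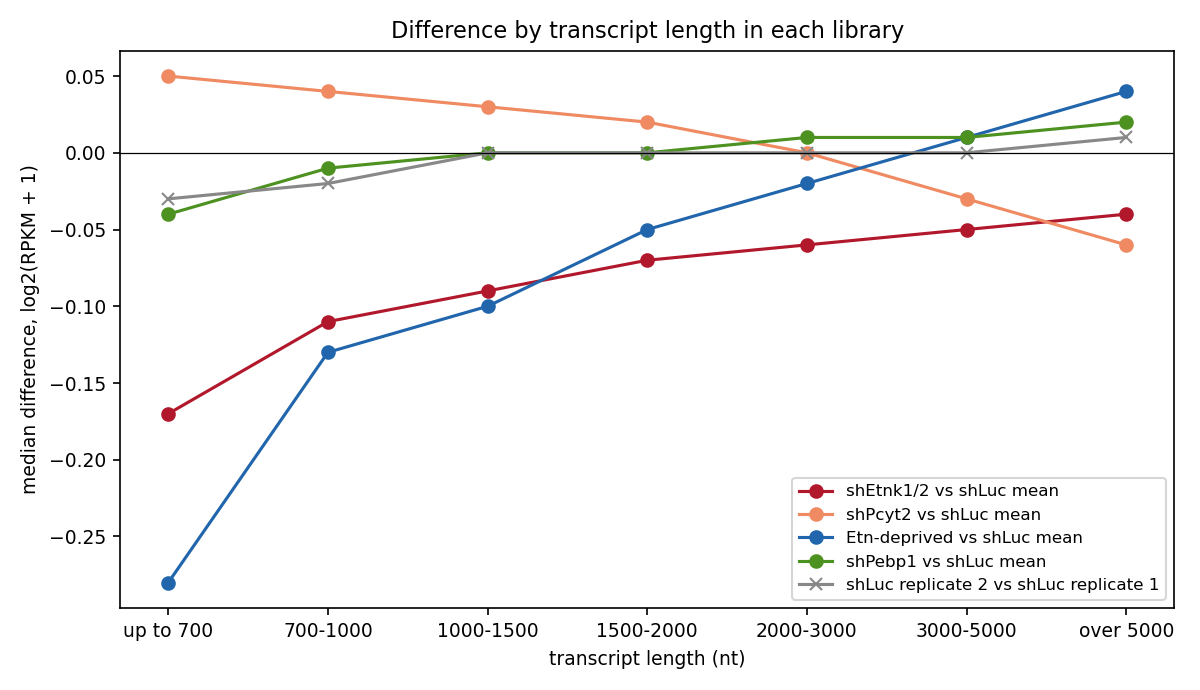
Median difference in log2(RPKM + 1) by transcript length (nt) for each treated library against the shLuc mean and for shLuc replicate 2 against replicate 1. In the Etn-deprived library the median went from -0.28 for transcripts of up to 700 nt to 0.04 for those over 5000 nt, and in shPcyt2 from 0.05 to -0.06.

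The shPebp1 library asked what knockdown of a protein that binds phosphatidylethanolamine does. Few genes were called, with Pebp1 as low in the library labelled shLuc replicate 2. Ubb, a ubiquitin gene, fell from 70.1 and 68.8 to 24.8 RPKM (-1.45, SE 0.07, adjusted p = 2.09e-05), as did Myl6 (-0.65, SE 0.06, adjusted p = 0.00124). Both were named after their values were seen. They were among 12 genes called by limma (1 higher, 11 lower), of which 9 were small RNAs. Interferon response genes had a median of 0.18 (percentile 100), with 16 of 21 higher and none called, or 2 adjusted over the list alone; Cxcl10 was at 0.93 (SE 0.21, adjusted p = 0.323) and Rtp4 at 0.56 (adjusted p = 0.175). Against shLuc replicate 1 alone the median was 0.08 (percentile 94.7), within the range of random lists. The reprogramming factors had a median of -0.20 (percentile 0.1), with Klf4 at -0.21 and Sox2 at -0.18 and none called, or 2 adjusted over the list alone. Mesenchymal and epithelial medians were both -0.02 (percentiles 5.3 and 31.5). Genes of cholesterol and fatty acid synthesis were at 0.10 (percentile 100), as they were in shLuc replicate 2 against replicate 1.

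The size rule took 24 genes in shPebp1, 23 of them small RNAs, with Mir425 (2.10), Mir8105 (1.82), Mir1249 (1.77), Mir466i (1.49) and Snord52 (1.13) highest and Mir467c (-2.91), Snord104 (-2.32), Mir3060 (-2.21), Mir5103 (-1.92) and Mir1964 (-1.77) lowest. Pebp1 itself was as low in the library labelled shLuc replicate 2. Without that library, and with the spread taken from the 3 pathway libraries, limma called 0 genes (231 at an unadjusted p under 0.05), where limma and limma-voom on all libraries called 12 and 13. Most of those 12 genes were not among the 13.

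The 3 libraries of pathway inhibition were compared with shLuc to find what they shared. All 4 reprogramming factors were lower in each of the 6 pairs of a treated and a shLuc library, which chance gives for either direction in 20% of genes, and the list had a median of -0.38. Of the 11939 genes tested, 23.7% lay on 1 side in all pairs, 1896 lower and 934 higher. Values were -0.49 (SE 0.12) for Klf4, -0.44 (SE 0.13) for Sox2 and -0.32 (SE 0.12) for Pou5f1. The shPebp1 library, not part of this comparison, also had all 4 factors below both shLuc libraries. Its values were 326.6 RPKM for Klf4, 270.2 for Sox2, 549.4 for Pou5f1 and 6.74 for Myc. The fall was therefore not particular to pathway inhibition. Interferon response genes had a median of 0.19, with 7 of 21 higher in all 6 pairs, among them Cxcl10 (0.79, SE 0.20) and Rtp4 (0.52, SE 0.12). Cxcl10 and Rtp4 also lay above both shLuc libraries in shPebp1, at 1.56 and 12.3 RPKM. Mesenchymal genes had a median of 0.15, with 12 of 32 higher in all pairs and Postn at 0.54 (SE 0.19). TGF-beta targets had a median of 0.16, with 7 of 18 higher in all pairs, including the inhibitory Smad6 (0.43, SE 0.13), and epithelial genes had a median of -0.24, with 5 of 13 lower in all pairs and Cdh1 at -0.25 (SE 0.19). No gene passed limma here (0 called, 724 at an unadjusted p under 0.05; limma-voom 0, with 810), and the mean of the 3 coefficients in the model of 5 groups gave 140 calls, or 7 with length adjusted, 27 with GC content and length, 5 with plain empirical Bayes, 0 without a filter (2696 at an unadjusted p under 0.05) and 545 with at least 50 reads. Adjusted over the list alone, 3 reprogramming factors, 2 interferon response genes and 1 CDP-ethanolamine pathway gene passed. The last was Pcyt2, itself the target of the shRNA in shPcyt2. Without shPcyt2 limma called 8 genes, among them Sox2 (-0.58) and Klf4 (-0.60).

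With the preset correlation, camera called 6 of 22 lists. These were the mesenchymal genes (up, adjusted p = 3.01e-09), the interferon response (up, adjusted p = 5.77e-08), TGF-beta targets (up, adjusted p = 5.72e-05), the reprogramming factors (down, adjusted p = 0.000941), endoplasmic reticulum stress (up, median 0.09, adjusted p = 0.00508) and epithelial genes (down, adjusted p = 0.0126). None of the calls held when the correlation was estimated (adjusted p = 0.56 with an estimated correlation for mesenchymal genes, 0.631 for epithelial genes and 0.545 for the other 4 lists). Without shEtnk1/2 the epithelial and endoplasmic reticulum stress lists were not called (adjusted p = 0.153 and 0.0593), nor was the epithelial list without shLuc replicate 1 or with GC content and length adjusted (adjusted p = 0.0658 and 0.0824; 0.00536 to 0.631 over its alternatives) or the endoplasmic reticulum stress list without shLuc replicate 2 (adjusted p = 0.0653; 0.00153 to 0.545). The lists for neural and glial genes (median -0.19, adjusted p = 0.0978), oxidative phosphorylation (-0.07, adjusted p = 0.0978), the cell cycle (-0.08, adjusted p = 0.116) and adipocytes (0.15, adjusted p = 0.189) were not called.

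The other 12 lists had medians between -0.08 and 0.02 and adjusted p from 0.382 to 0.867. They were cholesterol and fatty acid synthesis (-0.01), p53 targets (0.00), NF-kB targets (-0.03), autophagy (-0.03), glycolysis (-0.06), the integrated stress response (-0.02), skeletal muscle (0.00), pluripotency (-0.08), macrophages (-0.07), the CDP-ethanolamine pathway (-0.08), cartilage (0.02) and other phospholipid synthesis (-0.02). For NF-kB targets, autophagy, macrophages and cholesterol and fatty acid synthesis the test pointed up while the median lay below 0, and for cartilage it pointed down while the median lay above. Within the CDP-ethanolamine list, Pcyt2 was lower in all 6 pairs (-0.31, SE 0.09). It is the shRNA target in shPcyt2, and was at 86.6% and 81.5% of the shLuc mean in shEtnk1/2 and Etn-deprived. Endothelial, keratinocyte and histone lists had 2 measured members each and the mitochondrially encoded list 0, too few to test. Past the size rule in all pairs were 2 small RNAs with few reads, neither called by limma. Mir335 (2.09, SE 0.22, limma adjusted p = 0.059) had 0 and 0 reads in shLuc and 7, 4 and 8 in shEtnk1/2, shPcyt2 and Etn-deprived. Mir6385 (-1.59, SE 0.26, limma adjusted p = 0.546) had 7 and 7 against 0, 1 and 2.

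**Figure D4:**
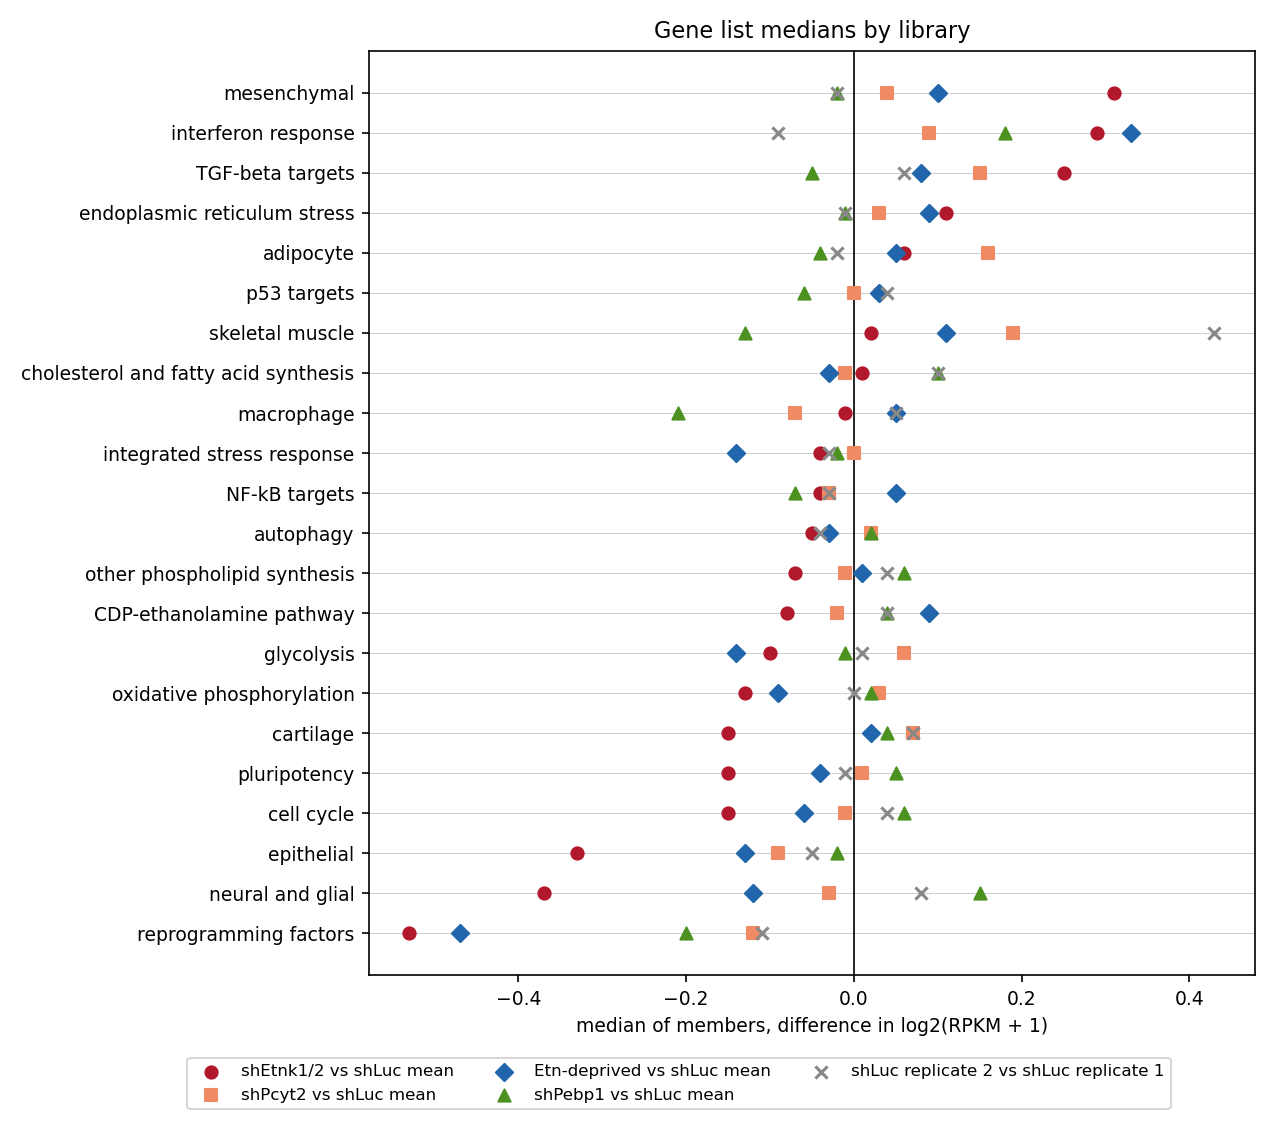
Median difference in log2(RPKM + 1) of the measured members of 22 gene lists in each treated library against the shLuc mean, and in shLuc replicate 2 against replicate 1 (crosses). Reprogramming factors were lowest in shEtnk1/2 (-0.53) and Etn-deprived (-0.47), and interferon response genes were at 0.29 and 0.33 in these libraries and at -0.09 in shLuc replicate 2 against replicate 1.

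The treatments were then compared with one another. The shEtnk1/2 and Etn-deprived libraries shared 17 genes called higher and 78 called lower, where independent lists give 0.8 and 9.1, but both lists rest on the same 2 shLuc libraries and so share genes by chance more often than that. Across genes their differences had r = 0.48, against 0.33 for simulated unchanged libraries with the same controls. With each set against a different shLuc library r was 0.31 and 0.27. The simulated libraries had the spread of the shLuc pair, and a treated library that varies more lowers r, though not the covariance. The covariance here was 0.0191, against 0.0066 to 0.0071 for unchanged libraries. For shEtnk1/2 and shPcyt2 r was 0.39 (covariance 0.0105), and 0.14 and 0.15 with different controls. For shPcyt2 and Etn-deprived r was 0.13 (covariance 0.0035), both below the values for unchanged libraries, and -0.05 and -0.09 with different controls. To ask whether shPebp1 resembled pathway inhibition, genes called in the others were followed into the shPebp1 library. Of 391 called in shEtnk1/2 that were not small RNAs, 172 (44.0%) went the same way in shPebp1, and of 427 called in Etn-deprived, 336 (78.7%) did, by a median of 0.09. Simulated unchanged libraries that share the controls went the same way in 65.3% of all genes, and no such value was made for called genes. Differences were ordered by GC content in shPebp1 too (Spearman rho -0.22), as in Etn-deprived (-0.52) and shEtnk1/2 (-0.18), and by 0.11 in shPcyt2. Neither these shares nor the values of r were adjusted for GC content, so a shared trend with it cannot be told apart. For shPebp1, r was 0.06 with shEtnk1/2, 0.08 with shPcyt2 and 0.29 with Etn-deprived, against 0.33 for unchanged libraries. With different controls it was 0.09 and 0.04 for shPebp1 and Etn-deprived, above the range of -0.02 to 0.03 for unchanged libraries, as was their covariance (0.0079 against 0.0066 to 0.0071), and 0.08 and 0.01 with the length trend removed. For shEtnk1/2 and shPcyt2 it lay below that range (-0.08 and -0.16, -0.12 and -0.23). In the simulated libraries each gene was drawn independently, without trends over the library in length or GC content. A value outside their range therefore does not show a shared effect of treatment. No gene other than small RNAs passed the size rule in pathway inhibition, so the planned count of such genes in shPebp1 was 0.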

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

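The tests on short genes in the Etn-deprived library, the test of a scale change in shEtnk1/2 and the fits adjusted for length or GC content were chosen only after the result was seen. The other tests of this part were written down before their results.

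Pairs of treatments were compared by a limma test of the difference itself, with 1 library on each side and the spread from the shLuc pair, so variation between cultures of a treatment was not measured. Between shEtnk1/2 and shPcyt2, 110 genes differed, 20 higher and 90 lower in shEtnk1/2, with Aspn at 0.64, Lum at 0.57, Tmprss5 at -1.13, Acsbg1 at -1.09 and Mapt at -1.07. Scaling to a common median ratio left 14 (5 higher, 9 lower), and adjustment for GC content and length 5. Between shEtnk1/2 and Etn-deprived, 102 genes differed, 57 higher and 45 lower in shEtnk1/2, with Myl6 at 1.02, Tmsb10 at 1.00, Id1 at 0.72, Cml3 at -1.31, Trh at -1.13 and Cebpd at -1.08, and 59 after adjustment for GC content and length. Between shPcyt2 and Etn-deprived, 385 genes differed, 326 higher and 59 lower in shPcyt2, with Gm5148 at 2.20 and Myl6 at 1.35, and 46 after that adjustment. With plain empirical Bayes the counts of the 3 pairs were 0, 5 and 9, and without a filter 0 in each (2383, 2597 and 2954 at an unadjusted p under 0.05), while limma-voom gave 253 (91 higher, 162 lower), 366 (150 and 216) and 741 (375 and 366), so the share of genes higher depended on the method.

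In the Etn-deprived library genes with short transcripts were low, at a median of -0.28 for those of up to 700 nt. Genes of oxidative phosphorylation as the whole source were argued against, since the 204 short genes outside this group had a median of -0.26 (95% gene bootstrap interval -0.32 to -0.20), beside -0.46 for the 41 within it, and so was GC content, since genes of up to 700 nt lay at -0.25 (interval -0.29 to -0.23) from genes over 2000 nt matched on GC content. A trend with length over the whole library cannot be told apart from a change of the shortest genes: genes of 1000 to 1500 nt lay at -0.06 (interval -0.08 to -0.05) from genes of 3000 to 5000 nt matched on GC content, an interval that reached the bound of 0.05 set for it. Removal of the trend took the median of the 384 lower calls from -0.48 (SE 0.08) to -0.36 (SE 0.08) and of the 70 higher calls from 0.45 to 0.46 (-0.33 and 0.35 with GC content and length removed), and since the prior degrees of freedom also fell, from 9.24 to 6.03, the calls lost do not measure it. Whether the pattern came from the making of this library or from Etn deprivation, which may also lie behind other changes, stays open because the condition had 1 library.

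Mesenchymal genes were high in the shEtnk1/2 library, at a median of 0.31. Removing the trend with length left a median of 0.30 at percentile 100 among random lists and removing GC content and length 0.31 at percentile 100, and the list lay 0.37 (95% gene bootstrap interval 0.28 to 0.42) above the median of all genes, where a change of scale moves all genes alike, so none of these is the whole source. An effect of low reprogramming factors alone cannot be told apart. The mesenchymal median of Etn-deprived differed by -0.21 (95% gene bootstrap interval -0.31 to -0.14) from that of shEtnk1/2, and Sox2 by -0.06 (SE 0.07) and Klf4 by -0.14 (SE 0.08). By the rule written beforehand, which named only Sox2 and Klf4, an interval without 0 argued against this effect. The rule was set aside after the values were seen, because Pou5f1 was less low, by 0.20 (SE 0.08, limma unadjusted p = 0.0311, adjusted p = 0.299). The shRNAs against the ethanolamine kinases may raise these genes, as a hypothesis found and tested on the same data. A larger share of cells that took up no factors, or a difference between cultures, was not tested and stays open with 1 library.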

How the results depend on the processing

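The minimum of 50 reads, removal of small RNAs, adjustments for length or GC content, limma-voom, list tests without a treated library and fits without shLuc replicate 2 were chosen after seeing the data; the other alternatives were planned, and all were run. No paired analysis was made, because only shLuc carries replicate numbers and the labels name no batch. In sample order, shEtnk1/2 and shPcyt2 followed shLuc replicate 1, and Etn-deprived and shPebp1 followed shLuc replicate 2. Each lay slightly nearer to that shLuc library by mean squared log2 distance. Distances were 0.0472 against 0.04891 for shEtnk1/2, 0.02306 against 0.02503 for shPcyt2, 0.04556 against 0.04682 for Etn-deprived and 0.02225 against 0.02664 for shPebp1. Whether this order marks batches that make libraries alike was not tested.

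The count called by limma in shEtnk1/2 (413) was 176 with GC content and length adjusted, 94 with length, 240 with a common median ratio, 153 with quantile normalization, 918 with at least 50 reads, 830 without small RNAs, 790 with limma-voom, 3 with plain empirical Bayes, 0 without a filter, and 5 without shLuc replicate 2. In Etn-deprived (454) the counts in the same order were 59, 40, 261, 197, 925, 868, 700, 13, 0 and 20. In shPcyt2 (13) the count was 8 with length adjusted, 5 with a mean of at least 5 RPKM, 5 with plain empirical Bayes, 37 with limma-voom, 0 without a filter, and 0 without shLuc replicate 2. In shPebp1 (12) it was 7 with GC content and length adjusted, 6 with length, 22 with at least 50 reads, 7 with plain empirical Bayes, 0 without a filter, and 0 without shLuc replicate 2. In the pathway comparison (0) it was 5 without a filter, 1 with a pseudocount of 0.1, 140 with the mean of 3 coefficients (7 with length adjusted too, 50 with a common median ratio, 33 with quantile normalization, 485 with limma-voom), and 0 to 8 when single libraries were left out, the 8 being without shPcyt2. Without a filter the prior degrees of freedom of the model of 5 groups were 0.61 against 9.24 in the reported fit, 6.03 with length and 7.07 with GC content and length adjusted, and with fewer small RNAs tested they were 27.2 (small RNAs out) or 33.94 (50 reads). Without shLuc replicate 2 the spread also held differences between treatments. For the other changes the cause was not tested.

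Counts past the size rule followed the pseudocount and the filter, as small RNAs with few reads made up most of them. For shEtnk1/2 (26), shPcyt2 (16), Etn-deprived (33), shPebp1 (24) and the pathway comparison (2), a pseudocount of 0.1 gave 70, 34, 69, 47 and 8, a pseudocount of 5 gave 1, 2, 4, 3 and 0, no filter gave 40, 34, 51, 47 and 4, a mean of at least 5 RPKM gave 7, 3, 10, 5 and 0, at least 50 reads gave 8, 0, 7, 1 and 0, and small RNAs left out gave 10, 0, 7, 1 and 0. Against 1 shLuc library alone the counts were 66 to 68, 47 to 49, 62 to 73, 44 to 58 and 7 to 8.

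The 6 lists called by camera went to 0 with an estimated correlation and stayed at 4 to 8 under the other alternatives; single lists stayed called in 49 instances, were lost in 11 and reversed in 0. With different shLuc libraries for each treatment, r went from 0.39 to 0.14 and 0.15 for shEtnk1/2 and shPcyt2, from 0.48 to 0.31 and 0.27 for shEtnk1/2 and Etn-deprived, from 0.29 to 0.09 and 0.04 for Etn-deprived and shPebp1, from 0.06 to -0.08 and -0.16 for shEtnk1/2 and shPebp1, from 0.13 to -0.05 and -0.09 for shPcyt2 and Etn-deprived, and from 0.08 to -0.12 and -0.23 for shPcyt2 and shPebp1. Removal of the shared control lowers r by construction. Of the values of single named genes under an alternative, 1768 kept their side of the threshold, 293 no longer passed, 34 newly passed and 0 reversed. Etnk2 (15 to 45 reads), most pluripotency genes and most small RNAs had few reads.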

Other observations

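All 3 tests on Pebp1 in this part were chosen only after the result was seen; the values in the next paragraph are descriptive and carry no test of an explanation.

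Several gene groups outside the transition between mesenchymal and epithelial cells also stood apart in single libraries. In shEtnk1/2, endoplasmic reticulum stress genes had a median of 0.11 (percentile 100), with 14 of 19 higher and none called by limma, and oxidative phosphorylation genes were lower in 25 of 25 cases, with a median of -0.13 (percentile 1.0, or 7.4 among lists matched on length too) and Cox5b called (-0.38, adjusted p = 0.0256). The p53 targets had a median of 0.03 (percentile 98.9) but a mean of -0.04, and the stress cytokine gene Gdf15 fell (-0.67, SE 0.12, adjusted p = 0.0197). With the length trend removed neither Cox5b nor Gdf15 passed (adjusted p = 0.129 and 0.0694). In the Etn-deprived library, without adjustment for its trends with length and GC content, glycolysis genes had a median of -0.14 (percentile 1.5), with 16 of 18 lower. The integrated stress response was at -0.14 (percentile 0.9), with 14 of 18 lower, and endoplasmic reticulum stress at 0.09 (percentile 98.8), with 14 of 19 higher. In shPcyt2, glycolysis genes were at 0.06 (percentile 97.8). In shPebp1, p53 targets had a median of -0.06 (percentile 0.6), with 17 of 20 lower, macrophage genes -0.21 (percentile 0.4), neural and glial genes 0.15 (percentile 99.6), cell cycle genes 0.06 (percentile 99.3), TGF-beta targets -0.05 (percentile 2.0) and NF-kB targets -0.07 (percentile 2.2). Of the 22 lists, 10 lay outside the central 95% of random lists in shEtnk1/2, 4 in shPcyt2, 6 in Etn-deprived and 9 in shPebp1, or 6 in shPebp1 against shLuc replicate 1 alone, beside 3 in the shLuc pair. Skeletal muscle genes were 1 of those 3 (0.43, percentile 99.7). With the length trend removed the counts for the treated libraries, in the same order, were 9, 4, 4 and 9, beside 4 in the shLuc pair. With GC content and length removed they were 9, 6, 4 and 7, beside 3.

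Pebp1 was at 100.7 RPKM in the library labelled shLuc replicate 2 and at 99.6 RPKM in shPebp1, against 250.4 in shLuc replicate 1. Chance variation of a single gene was argued against, since of 4611 genes with at least 1000 mean reads Pebp1 was the only 1 that differed as much between the shLuc libraries, the next largest log2 difference being 0.65. A swap of the shLuc replicate 2 and shPebp1 labels was argued against as the source of the low value, since Pebp1 was low in both. Its ratio in shPebp1 to shLuc replicate 1 was 0.398 (95% interval 0.372 to 0.426). Whether the labels were exchanged cannot be told from Pebp1, as its level was alike in these 2 libraries. Whether the library labelled shLuc replicate 2 may hold cells with Pebp1 knocked down cannot be told apart from a control library: over other genes its mean squared distance to shPebp1 minus that to shLuc replicate 1 was -0.00087 (95% gene bootstrap interval -0.00197 to 0.0002), and knockdown of Pebp1 might move few other genes. If it does hold such cells, every comparison with shLuc rests on 1 true control.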
